A study of Mus musculus with 8 samples.

How the data were processed

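PolyA RNA was measured by sequencing in 8 libraries of sorted mouse leukemia macrophages, 4 from cultures of macrophages alone (Mac) and 4 from 12 h co-cultures with mesenchymal stromal cells (E-Mac). RNA was prepared with the RNeasy micro kit and on-column DNase, and libraries with the VAHTS mRNA-seq V3 kit. The authors deposited 1 table of raw counts, reads per gene symbol, with 1 column per library. The submitters' processing notes name bcl2fastq, HISAT2, featureCounts, Subread and DESeq2, without versions, and the genome build mm10. The annotation release and the strand and multi-mapping settings are not given in the sources used here, so reads that match several gene copies may be missing or shared in an unknown way. Total counts were 15096159, 11646025, 15556935 and 15399524 in Mac 1 to 4 and 13377046, 15649620, 15740846 and 14361275 in E-Mac 1 to 4.

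The table held 53673 names. Of these 26 had the form of dates, which spreadsheet programs make of some gene symbols (2 names stood more than once). They held 0.133 to 0.160% of the counts of a library and were left out. The 37 mitochondrial genes had 0 counts in every library, so mitochondrial transcripts were not analysed here. Of the 53647 genes left 25583 had a count. Gene coordinates were taken from GENCODE M21 on mm10, which held 52966 of the names and 99.2% of the genes tested. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of at least 4.86 over genes with 20 counts or more).

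Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, minimum total 15), TMM factors (1.03 to 1.07 in Mac and 0.931 to 0.970 in E-Mac), a robust quasi-likelihood fit of the group, and Benjamini-Hochberg adjustment over the 13412 genes tested, with calls at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. CPM are counts per 1000000, taken over each library's total in the tested genes multiplied by its TMM factor. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg over the 39 lists that had 5 or more tested members, and again with an estimated correlation. Marker sums were compared with an exact two-sided permutation test, whose smallest p for 4 against 4 libraries is 0.0286. A fold against a group with 0 counts was taken against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with a 95% interval was used. Tested on simulated data with 4 against 4 libraries, edgeR recovered 59.7, 82.1 and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold, and called 8 unchanged genes. Only 200 of the 13412 genes were changed there, whereas 58.3% were called in the data, so these rates need not hold for the real comparison.

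The groups, tests, alternatives, lists and the rule for named genes were fixed before the data were examined. The 25 pathway lists were alternative activation and tissue repair, classical activation, type I interferon response, chemokines, NF-kB feedback and signalling, cAMP and prostaglandin E2 response, STAT3 response, immediate early and dissociation stress, MHC class II presentation, MHC class I presentation, phagocytic and scavenger receptors, lysosome, glycolysis, hypoxia response, mitochondrial respiratory chain (nuclear-encoded), cholesterol synthesis, LXR targets and lipid handling, NRF2 and heme and iron handling, unfolded protein response, cell cycle, trophic and angiogenic factors, matrix proteases and inhibitors, immune checkpoint and suppressive molecules, receptors for stromal signals and apoptosis regulators. The 16 marker lists were macrophage core markers, monocyte markers, stromal (MSC and fibroblast) markers, neutrophil and granulocyte markers, dendritic cell markers, B cell markers, T and NK cell markers, erythroid and megakaryocyte markers, mast cell and basophil markers, eosinophil markers, endothelial markers, osteoclast markers, stem and progenitor markers, ribosomal proteins, mitochondrially encoded transcripts and sex-linked transcripts. The named genes were the 8 largest increases and 8 largest decreases among genes with an adjusted p under 0.05, at least 10 CPM in the higher group, groups that did not overlap and a symbol that was not a numbered gene model. To these came the 3 members with the smallest adjusted p of each pathway list, the 2 of each marker list, and 14 genes named whatever their values. Not each gene that the rule gave is printed. The alternatives were RLE factors, upper-quartile factors, library size only, no filter, at least 10 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit without the robust option, an adjusted p threshold of 0.01, a test against a fold of 1.5, a stromal marker score as a covariate, each library left out in turn, fry, and the lists without stromal marker genes. The stromal sum was also taken without its highest member and over collagen genes only. Leaving out E-Mac 2 and 4, 9 further lists and a list of glucocorticoid-induced genes were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.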

Results

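Gene counts were available for 8 polyA RNA libraries of C57BL/6 mouse leukemia macrophages, each sorted after 12 h in culture. In 4 libraries the macrophages had been kept alone (Mac). In the other 4 they had shared the dish with mesenchymal stromal cells (MSC, fibroblast-like cells that support blood formation) and are called E-Mac here, for MSC-educated macrophages. The comparison asks which transcripts of the sorted cells differ after that co-culture. In Mac, 21 granulocyte markers summed to 37042 CPM and 20 macrophage core markers to 22853, against 15485 and 21824 in E-Mac. A changed mix of cells in the sort was not separated from changes within the macrophages. Total counts per library ran from 11646025 to 15556935 in Mac and from 13377046 to 15740846 in E-Mac, with 18485 to 19720 genes detected. The labels do not say that the libraries came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. Values in parentheses after a gene are its log2 fold change, E-Mac over Mac, ± its standard error (n = 4 and 4). CPM are counts per 1000000 counts of a library, its total over the tested genes scaled by the TMM factor, as mean ± SD over 4 libraries.

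E-Mac carried far more Arg1, the arginine-hydrolysing enzyme of alternatively activated macrophages, at 303 ± 115 CPM against 0.373 ± 0.334 in Mac. The monocyte-attracting chemokine Ccl7 stood at 309.8 ± 127 against 0.290 ± 0.252 CPM, and Cd274, which encodes the checkpoint ligand PD-L1, at 427 ± 26.2 against 31.8 ± 4.56. All 30 tested genes of the type I interferon list and all 20 of the MHC class I list rose. Of the 38 cell cycle genes 29 fell, as did 10 of 15 MHC class II presentation genes. The granule protein genes Camp and Fcnb fell (-2.91 ± 0.14 and -3.40 ± 0.12). Of 13412 genes tested, 7814 (58.3%) differed, 3954 higher and 3860 lower in E-Mac, and 2695 of them by 2-fold or more (1283 higher, 1412 lower). Higher genes were 50.6% of the calls with TMM factors, and 37.4% (2996 higher, 5018 lower) when libraries were scaled by total counts only, which moved the median log2 fold change by -0.14. In 7232 tested genes (53.9%) all 4 libraries of one group lay above all 4 of the other, which chance gives for 2.86%. Without E-Mac 2 and 4, the libraries with the most stromal marker counts, 8496 genes differed, and 7160 of the 7814 kept their call and direction. These 2 libraries also stood apart from E-Mac 1 and 3 on the second principal component (20.6 and 28.9 against -26.2 and -22.0). Leaving them out therefore changes more than the stromal share. E-Mac 1 and 3 lay close to each other (chi-square per degree of freedom 4.91, against 19.9 to 34.4 with E-Mac 2 and 4). The smaller spread that remains may add calls.

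Among well-expressed genes the largest increases, by a rule set in advance, included Ramp3, an accessory protein of calcitonin-family receptors, and the fibrillar collagen gene Col3a1. Both had 0 counts in Mac, and their 10.6 ± 2.03 and 10.6 ± 9.89 CPM in E-Mac were at least 215-fold and 216-fold higher, with a floor of 3 counts over the Mac group. Ramp3 ran from 8.69 to 12.7 CPM in the E-Mac libraries, whereas Col3a1 stood at 19.0 and 19.2 CPM in E-Mac 2 and 4 and 2.18 and 1.82 in E-Mac 1 and 3. Ccl7 (10.15 ± 0.58), Arg1 (9.73 ± 0.56), the collagenase Mmp13 (8.45 ± 0.44) and the membrane protein Flrt2 (8.27 ± 0.37) also rose. The platelet chemokine Ppbp rose from 2 counts, both in Mac 3, to 42.4 ± 16.3 CPM, a ratio of 1277 (95% counting interval 353 to 10554). Col5a2, another collagen gene, rose from 2 counts in Mac 3 to 18.1 ± 16.5 CPM, a ratio of 554 (153 to 4580.1). Without Mac 3 both genes had 0 counts in Mac. Col5a2 was 28.1 and 36.2 CPM in E-Mac 2 and 4 and 4.29 and 3.97 in E-Mac 1 and 3. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.0360 for Col3a1 and at most 0.00269 for the others of these 8. Each was higher in 4 of 4 E-Mac libraries, as the rule required. The Col3a1 call was lost without E-Mac 1, E-Mac 2 or E-Mac 4 and with no filter (adjusted p = 0.0603, 0.0726, 0.108 and 0.0921, 1.75e-08 to 0.108 over all alternatives). Without Mac 2 the values were 10.81 for Ccl7 and 8.91 for Flrt2.

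The 8 largest decreases began with the lipid transporter gene Abca6 and the globin genes Hbb-bs and Hba-a1. They held 29.5 ± 1.63, 26.6 ± 5.13 and 14.9 ± 4.12 CPM in Mac and 0 counts in E-Mac, at least 553-fold, 506-fold and 273-fold lower with the same floor over the E-Mac group. The lectin receptor Cd209a (-6.52 ± 0.38), the histone gene Hist1h2bg (-5.37 ± 0.21), the transporter Abca9 (-5.27 ± 0.10), the acute-phase protein Orm1 (-4.98 ± 0.19) and the cytochrome P450 gene Cyp2ab1 (-4.90 ± 0.17) fell as well. All 4 E-Mac libraries lay below all 4 Mac libraries for each of the 8, as the rule for naming them required, with an adjusted p of at most 7.84e-08 (edgeR, Benjamini-Hochberg). Without E-Mac 4 the value of Cd209a was -7.22. On mm10, Arg1 lies on chromosome 10, 24915221 to 24927484, Ccl7 on chromosome 11, 82045712 to 82047525, Abca6 on chromosome 11, 110176820 to 110251776, the neighbouring Abca9 on chromosome 11, 110100749 to 110168196 and Cd274 on chromosome 19, 29367455 to 29388095, each annotated as protein coding. How reads were shared between near-identical copies is not given in the sources used here. Values of the globin genes, Hspa1b, Ifit3, the Bcl2a1 and H2 genes, Ear1 and Ear2, Hist1h2bg and the ribosomal proteins are therefore uncertain.

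Of 14 genes fixed in advance whatever their values, Arg1 (9.73 ± 0.56), Nos2 (4.48 ± 0.46), Cd274 (3.75 ± 0.10), Vegfa (2.44 ± 0.10) and the macrophage surface gene Adgre1 (1.01 ± 0.08) rose, each in 4 of 4 E-Mac libraries (largest adjusted p = 2.53e-06). Nos2, the inducible nitric oxide synthase, remained low at 3.52 ± 0.590 CPM. The inflammatory cytokines Il1b (1.31 ± 0.19) and Tnf (1.01 ± 0.18) rose (adjusted p = 0.000206 and 0.000649), and so did the anti-inflammatory Il10 (1.49 ± 0.48), although its groups overlapped (adjusted p = 0.0165). Il6 was 1.79 ± 0.807 CPM in Mac and 3.20 ± 1.72 in E-Mac, a difference that did not pass (0.86 ± 0.39, adjusted p = 0.0752) but did without Mac 2 or E-Mac 1 (adjusted p = 0.0296 and 0.0294, 0.0277 to 0.717 over all alternatives). The mannose receptor gene Mrc1 (0.16 ± 0.36, adjusted p = 0.727) was 18.2 and 14.0 CPM in E-Mac 2 and 4 and 48.8 and 33.9 in E-Mac 1 and 3. Its value was -0.21 without E-Mac 1 and 0.70 without E-Mac 2 and 4 (adjusted p = 0.00128, 0.000856 to 0.994 over all alternatives). Ptgs2 (-0.48 ± 0.31, adjusted p = 0.219) and the growth factor receptor gene Csf1r (0.06 ± 0.09, adjusted p = 0.621) did not pass. Csf1r was -0.087 with total counts only and -0.042 with upper-quartile factors. Col1a1, the main collagen gene of fibroblasts, rose from 1.13 ± 0.250 to 80.3 ± 70.6 CPM (6.17 ± 1.11, adjusted p = 0.00276), with 141 and 142 CPM in E-Mac 2 and 4 and 23.2 and 15.2 in E-Mac 1 and 3. Cxcl12, a stromal chemokine, was too low to test, at 1.35 ± 0.761 CPM in Mac and 0.208 ± 0.139 in E-Mac.

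**Figure D1:**
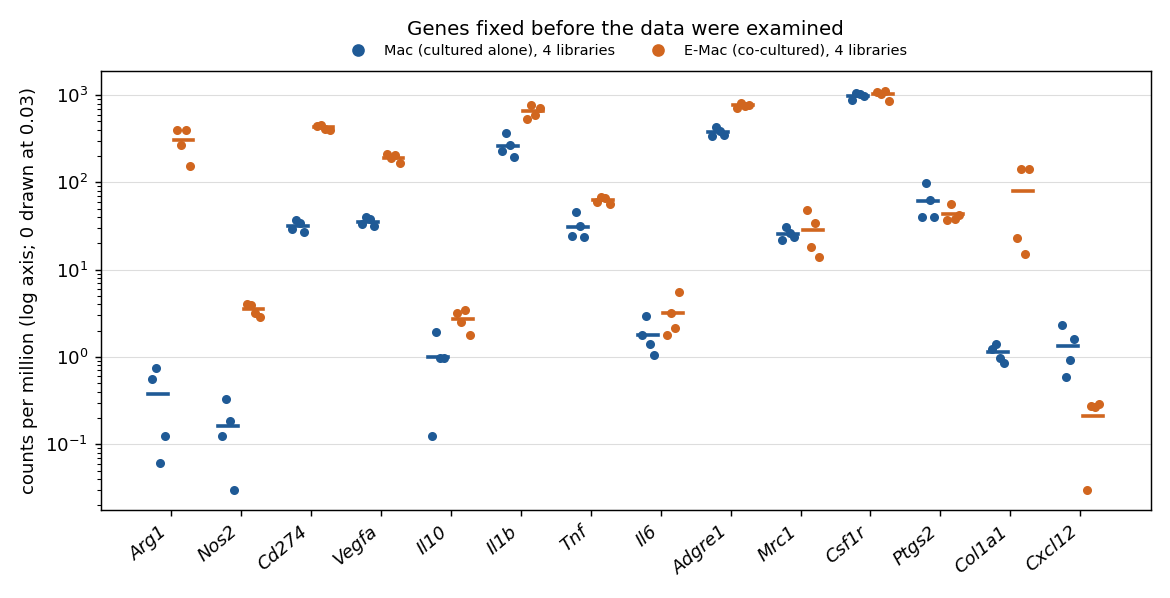
CPM (log axis) of the 14 genes fixed in advance, with each point a library and each line a group mean (0 CPM drawn at 0.03). Arg1 stood between 156 and 395 CPM in the 4 E-Mac libraries and under 1 CPM in the 4 Mac libraries, while Csf1r overlapped between the groups.

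Of 39 gene lists fixed before the data were examined, 27 shifted relative to the other genes by camera with a preset correlation of 0.01, 18 up and 9 down, and 7 of the 27 held with an estimated correlation. Some lists share genes, so their calls are not independent. Another list also held 16 of the 29 alternative activation genes, 12 of the 28 classical activation genes and 0 of the 25 cholesterol synthesis genes. In 26 of the 27, the list mean of all 4 E-Mac libraries lay on the called side of all 4 Mac libraries; for the eosinophil list 3 of 4 did. Counts of members that rose or fell are over all 13412 genes tested, followed by the counts adjusted over the list alone. The members named as rising or falling had all 4 libraries of one group above all 4 of the other unless said. Members named where 5 or fewer of a list moved against the rest were chosen after their values had been seen, as were Loxl2, S100a9 and Ngp.

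Every one of the 30 type I interferon response genes rose (30 and 0 adjusted over the list alone), with a median log2 fold change of 1.89. They included the antiviral genes Rsad2 (3.57 ± 0.08), Ifit3 (3.55 ± 0.08) and Oasl1 (3.39 ± 0.08), and Rsad2 reached 1428 ± 94.0 CPM against 120.1 ± 6.01 (camera adjusted p = 1.84e-64, and adjusted p = 0.0214 with an estimated correlation). All 20 MHC class I presentation genes rose (20 and 0 adjusted over the list alone, median 1.22, adjusted p = 3.54e-18, and adjusted p = 0.0458 with an estimated correlation). Examples were the class I gene H2-T22 (1.91 ± 0.07), the peptide-loading factor Tapbp (1.51 ± 0.07) and the proteasome activator subunit Psme2 (1.31 ± 0.06). MHC class II presentation went down: 10 of 15 members fell and 2 rose (10 and 2 adjusted over the list alone, median -0.96, adjusted p = 0.0110, and adjusted p = 0.304 with an estimated correlation). The class II chain gene H2-Ab1 (-1.95 ± 0.14) and the invariant chain gene Cd74 (-1.61 ± 0.13) fell, while the 2 that rose were the lysosomal proteases Lgmn (2.99 ± 0.17) and Ctss (1.08 ± 0.11). The class II call was lost without E-Mac 4 (adjusted p = 0.0898) and without E-Mac 2 and 4 (adjusted p = 0.150, 0.000383 to 0.304 over all alternatives except fry), with a median of -1.15 and 10 of 15 members falling in the latter.

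In the classical activation list 21 of 25 genes rose and 1 fell (21 and 1 adjusted over the list alone, median 1.26, adjusted p = 4.15e-10, and adjusted p = 0.108 with an estimated correlation). The chemokine Ccl5 (5.34 ± 0.12), the transcription factor Irf1 (1.43 ± 0.07) and the costimulatory ligand Cd86 (1.53 ± 0.09) rose, and the chemokine Cxcl9 (-1.86 ± 0.28) fell. Il6 (0.86 ± 0.39), Il27 (-0.11 ± 0.14) and Gpr18 (-0.05 ± 0.11) did not pass. The alternative activation and tissue repair list was split, with 14 of 27 up and 11 down (15 and 11 adjusted over the list alone, median 0.60), and did not pass as a list (adjusted p = 0.169). Tgm2 (3.01 ± 0.08), a crosslinking enzyme, the interleukin-1 antagonist Il1rn (2.57 ± 0.08) and the scavenger receptor Stab1 (4.68 ± 0.18) rose with Arg1. The transcription factor Klf4 (-3.44 ± 0.12) and the chitinase-like Chil3 (-2.40 ± 0.10) fell. That list passed with the replicate number as a block (adjusted p = 0.00319), without E-Mac 4 (adjusted p = 0.0125) and without E-Mac 2 and 4 (adjusted p = 5.26e-06, 5.26e-06 to 0.574 over all alternatives except fry).

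Chemokine transcripts rose in 17 of 20 cases and fell in 1 (17 and 1 adjusted over the list alone, median 4.28, adjusted p = 3.97e-15, and adjusted p = 0.0509 with an estimated correlation). Ccl5 (5.34 ± 0.12), Cxcl16 (3.67 ± 0.13) and Cxcl14 (4.57 ± 0.22) had the smallest adjusted p, and Ccl5 reached 191 ± 16.8 CPM. Cxcl9 fell, and Cxcl1 (1.02 ± 0.83) and Cxcl2 (0.87 ± 0.51) did not pass. Among regulators of NF-kB, a transcription factor of inflammation, 17 of 24 rose and 3 fell (18 and 3 adjusted over the list alone, median 0.73, adjusted p = 2.32e-06, and adjusted p = 0.215 with an estimated correlation). The mitochondrial superoxide dismutase Sod2 (2.30 ± 0.08), Tnip3 (3.24 ± 0.17) and Traf1 (2.12 ± 0.12) rose, and Nfkb1 (-0.37 ± 0.06), Nfkbiz (-1.77 ± 0.29) and Ripk2 (-0.77 ± 0.10) fell. Of 24 checkpoint and suppressive molecules 21 rose and 1 fell (22 and 1 adjusted over the list alone, adjusted p = 2.74e-13, and adjusted p = 0.0372 with an estimated correlation). Cd274 (3.75 ± 0.10), Il1rn (2.57 ± 0.08) and the lectin gene Lgals9 (1.60 ± 0.08) rose, and Vsir (-0.58 ± 0.08), which encodes the checkpoint protein VISTA, fell.

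The cAMP and prostaglandin E2 response list moved in both directions, 10 of 24 up and 9 down (10 and 9 adjusted over the list alone, adjusted p = 0.731). Its median of 0.00 was -0.09 with upper-quartile factors and -0.14 with total counts only, and the camera direction turned, with no call, without Mac 1 or Mac 4 (adjusted p = 0.863 and 0.907, 0.336 to 0.949 over all alternatives except fry). The angiogenic factor Vegfa (2.44 ± 0.10) and the tetraspanin Cd9 (1.52 ± 0.11) rose and the co-regulator Cited2 (-1.27 ± 0.08) fell. In the STAT3 response list, genes induced by cytokines of the IL-6 family, 12 of 21 rose and 6 fell (12 and 6 adjusted over the list alone, median 0.37, adjusted p = 0.0544). Il1rn (2.57 ± 0.08) and the NF-kB cofactor Bcl3 (1.32 ± 0.08) rose and the receptor subunit Il6st (-1.25 ± 0.09) fell. The list passed without E-Mac 1 or E-Mac 3 (adjusted p = 0.0341 and 0.0383, 0.00388 to 0.532 over all alternatives except fry).

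Immediate early and dissociation stress genes, which respond within minutes to hours to handling or stimulation, fell in 16 of 24 cases and rose in 3 (18 and 3 adjusted over the list alone, median -0.94, adjusted p = 0.00468, and adjusted p = 0.574 with an estimated correlation). Fos fell from 3218 ± 719 to 829 ± 108 CPM (-1.96 ± 0.15), and the heat shock gene Hspa1b (-2.60 ± 0.24) fell. Egr2 (2.84 ± 0.18) and Ier3 (2.29 ± 0.22) rose in 4 of 4 E-Mac libraries, and Hsp90aa1 (0.52 ± 0.13) rose with overlapping groups. Without E-Mac 2 and 4 the list did not pass (adjusted p = 0.102, 5.52e-05 to 0.574 over all alternatives except fry), with a median of -1.01 and 12 of 24 members falling. Cell cycle genes fell in 29 of 38 cases and rose in 3 (29 and 3 adjusted over the list alone, median -1.13, adjusted p = 2.32e-06, and adjusted p = 0.532 with an estimated correlation). The transcription factor E2f2 (-1.19 ± 0.06), the mitotic activator Cdc20 (-1.64 ± 0.12) and the kinase Cdk2 (-0.87 ± 0.07) fell. The exceptions that rose were Ccnd1 (3.21 ± 0.24), which encodes the G1 cyclin D1, and the replication genes Gins2 (0.83 ± 0.19) and Cdt1 (0.32 ± 0.10, groups overlapping).

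**Figure D2:**
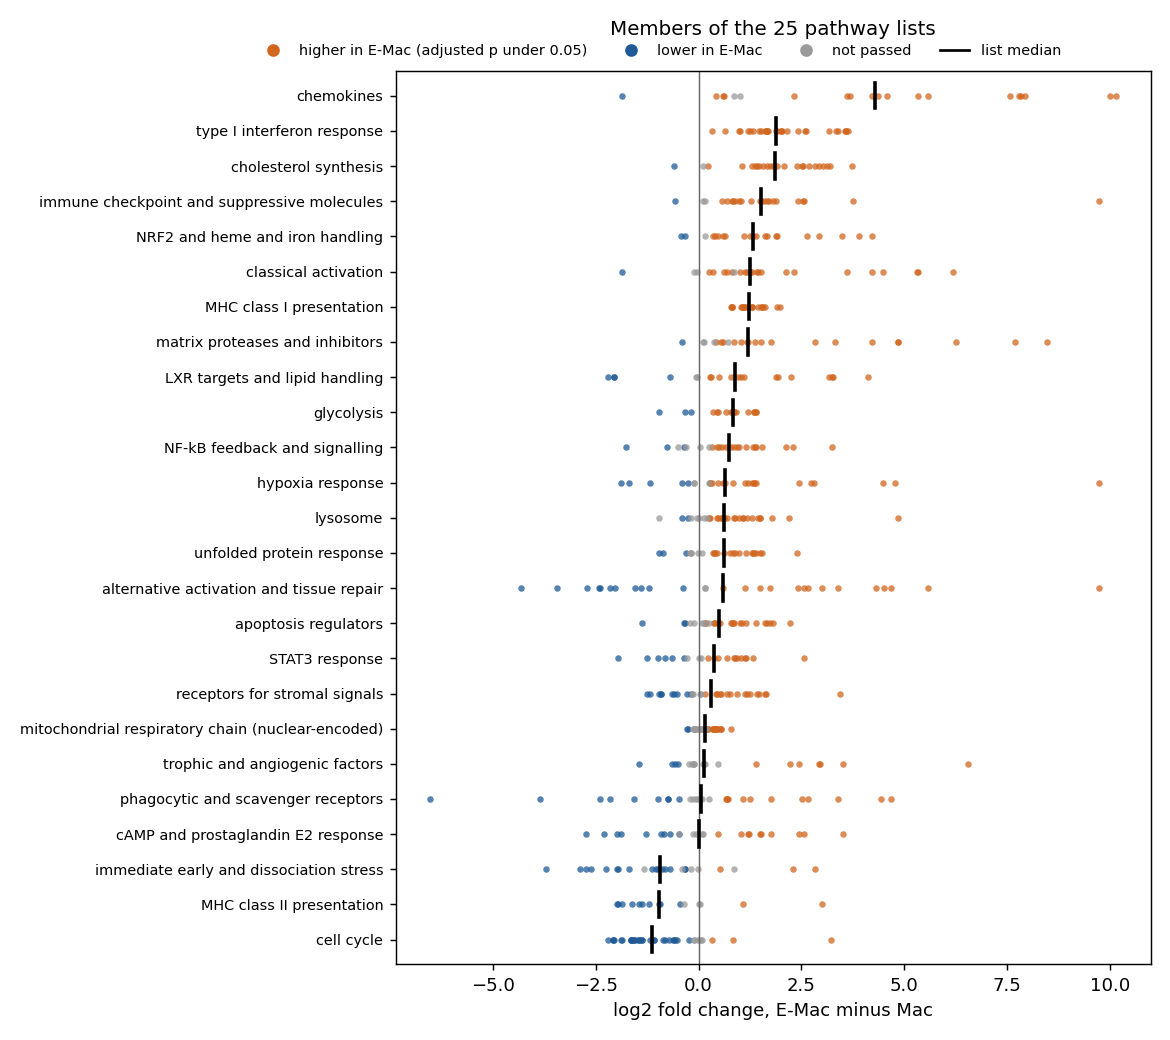
Log2 fold change (E-Mac minus Mac) of each tested member of the 25 pathway lists, with orange and blue points higher and lower at an adjusted p under 0.05, grey points not passed and a black tick at the list median. The medians ran from -1.13 for cell cycle to 4.28 for chemokines.

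Cholesterol synthesis genes rose in 22 of 24 cases and fell in 1 (22 and 1 adjusted over the list alone, median 1.86, adjusted p = 1.81e-19, and adjusted p = 0.145 with an estimated correlation). The sterol demethylase Cyp51 (3.19 ± 0.13) and the master regulator Srebf2 (1.42 ± 0.06) rose, and Tm7sf2 (-0.59 ± 0.17) fell. Of 20 LXR target and lipid handling genes 14 rose and 4 fell (14 and 4 adjusted over the list alone, median 0.87, adjusted p = 0.000777, and adjusted p = 0.167 with an estimated correlation). Arl4c (1.87 ± 0.09) and the fatty acid desaturase Scd1 (3.17 ± 0.18) rose, and the phospholipid transfer protein Pltp (-2.07 ± 0.12), Fabp4 (-2.06 ± 0.13), Apoc1 (-2.20 ± 0.32) and Apoe (-0.70 ± 0.11) fell. In the NRF2, heme and iron list, 18 of 21 genes rose and 2 fell (18 and 2 adjusted over the list alone, median 1.33, adjusted p = 1.39e-15, and adjusted p = 0.0372 with an estimated correlation). The antioxidant enzyme Srxn1 (3.89 ± 0.10), the cystine transporter Slc7a11 (3.49 ± 0.10) and the ferritin heavy chain Fth1 (2.94 ± 0.12) rose, Fth1 to 9235 ± 1124 CPM. The pentose phosphate enzymes G6pdx (-0.42 ± 0.06) and Tkt (-0.33 ± 0.06) fell.

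Glycolysis genes rose in 15 of 18 cases and fell in 3 (15 and 3 adjusted over the list alone, median 0.83, adjusted p = 2.68e-05, and adjusted p = 0.158 with an estimated correlation). The glucose transporter Slc2a1 (1.40 ± 0.06), the lactate exporter Slc16a3 (1.35 ± 0.08) and pyruvate kinase Pkm (1.40 ± 0.10) rose, while Pfkm (-0.97 ± 0.18), Pfkp (-0.34 ± 0.08) and Gpi1 (-0.18 ± 0.07) fell. Of 27 hypoxia response genes 19 rose and 5 fell (19 and 5 adjusted over the list alone, median 0.65, adjusted p = 0.000216, and adjusted p = 0.0372 with an estimated correlation). The oxygen-regulated transcription factor gene Hif1a (2.80 ± 0.07) and Vegfa (2.44 ± 0.10) rose, and Ndrg1 (-1.89 ± 0.08), Ddit4 (-1.68 ± 0.11), Bnip3l (-1.18 ± 0.07), Egln3 (-0.41 ± 0.12) and Pfkfb4 (-0.25 ± 0.08) fell. Loxl2 of this list was 4.54 and 6.25 CPM in E-Mac 2 and 4 and 1.95 and 1.01 in E-Mac 1 and 3, a split that the stromal collagens also had. Among nuclear-encoded respiratory chain genes 16 of 35 rose and 2 fell (15 and 2 adjusted over the list alone, median 0.16), but with total counts only 8 rose and 7 fell, and the list did not pass (adjusted p = 0.256). Cycs (0.80 ± 0.12), which encodes cytochrome c, Sdhb (0.54 ± 0.08) and Sdhd (0.36 ± 0.07) rose, and Uqcrh (-0.29 ± 0.08) fell. Without E-Mac 2 and 4 the list passed (adjusted p = 0.0403, 0.0403 to 0.781 over all alternatives except fry).

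Lysosomal genes rose in 22 of 30 cases and fell in 2 (22 and 3 adjusted over the list alone, median 0.62, adjusted p = 7.09e-07, and adjusted p = 0.357 with an estimated correlation). The protease Ctsd (2.20 ± 0.08), the cholesterol exporter Npc1 (80.2 ± 5.67 CPM in Mac and 227 ± 29.5 in E-Mac) and the acid lipase Lipa (1.31 ± 0.09) rose, and Hexa (-0.40 ± 0.08) and Ctsa (-0.25 ± 0.08) fell. Of 25 unfolded protein response genes, which encode chaperones and stress regulators of the endoplasmic reticulum, 17 rose and 3 fell (17 and 4 adjusted over the list alone, median 0.61, adjusted p = 0.00518, and adjusted p = 0.543 with an estimated correlation). Ddit3 (12.9 ± 2.67 CPM in Mac and 36.2 ± 3.06 in E-Mac), Calr (1.55 ± 0.14) and Pdia6 (1.33 ± 0.12) rose, and Dnajb9 (-0.96 ± 0.15), Chac1 (-0.86 ± 0.22) and Ero1lb (-0.30 ± 0.09) fell. Apoptosis regulators rose in 20 of 28 cases and fell in 3 (21 and 3 adjusted over the list alone, median 0.50, adjusted p = 0.000474, and adjusted p = 0.120 with an estimated correlation). Both the pro-apoptotic Bcl2l11 (1.38 ± 0.08) and the anti-apoptotic Bcl2a1d (1.66 ± 0.12) and Bcl2a1b (2.22 ± 0.18) rose, and Apaf1 (-0.34 ± 0.06), Xiap (-0.35 ± 0.07) and Pmaip1 (-1.38 ± 0.23) fell.

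Phagocytic and scavenger receptors went both ways, with 12 of 28 up and 9 down (12 and 9 adjusted over the list alone), and did not pass as a list (adjusted p = 0.301). Their median of 0.06 was -0.04 with upper-quartile factors and -0.08 with total counts only. Stab1 (4.68 ± 0.18), which rose from 17.5 ± 0.793 to 448 ± 111 CPM, and the integrin Itgav (1.07 ± 0.07) were higher and Cd209a (-6.52 ± 0.38) was lower. The list passed without E-Mac 4 (adjusted p = 0.0256) and without E-Mac 2 and 4 (adjusted p = 0.00501, 0.00501 to 0.668 over all alternatives except fry). Receptors for stromal signals rose in 16 of 30 cases and fell in 10 (16 and 11 adjusted over the list alone, median 0.30, adjusted p = 0.0628). The chemokine receptor Ccr1 (1.60 ± 0.06) and the interleukin receptor chain Il10rb (1.41 ± 0.07) rose. This list passed without E-Mac 1, E-Mac 3 or E-Mac 4 (adjusted p = 0.0323, 0.0355 and 0.0335, 0.00420 to 0.508 over all alternatives except fry).

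Matrix proteases and their inhibitors rose in 18 of 23 cases and fell in 1 (19 and 1 adjusted over the list alone, median 1.20, adjusted p = 7.92e-09, and adjusted p = 0.0372 with an estimated correlation). The membrane protease Mmp14 (6.26 ± 0.18), Adam8 (1.52 ± 0.08) and the matrix protein Tgfbi (1.38 ± 0.10) rose, and the heparanase gene Hpse (-0.41 ± 0.12) fell. Of 20 trophic and angiogenic factors 7 rose and 4 fell (7 and 4 adjusted over the list alone, adjusted p = 0.0275, and adjusted p = 0.158 with an estimated correlation). Spp1 (6.55 ± 0.32), which encodes osteopontin, Thbs1 (3.52 ± 0.20) and Vegfa (2.44 ± 0.10) rose, Thbs1 to 7637 ± 966 CPM. Inhba (-1.44 ± 0.19), Hgf (-0.57 ± 0.13) and Fgf2 (-0.64 ± 0.25) fell, and so did Pdgfb (-0.50 ± 0.20), whose groups overlapped. The median of this list was 0.13, but -0.02 with total counts only and -0.03 without E-Mac 2 and 4. The call was lost without Mac 1, E-Mac 2 or E-Mac 4 (adjusted p = 0.0555, 0.0625 and 0.0582, 0.00322 to 0.158 over all alternatives except fry).

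Markers of the cells that a sort of co-cultured macrophages could hold were summed per library. The sum of the macrophage core markers was 22853 ± 657 CPM in Mac and 21824 ± 1459.6 in E-Mac, a difference that did not pass an exact two-sided permutation test (p = 0.343). As a list, 13 of 20 rose and 4 fell (13 and 4 adjusted over the list alone, median 0.78, adjusted p = 0.000137, and adjusted p = 0.215 with an estimated correlation). The endotoxin co-receptor Cd14 (2.57 ± 0.10) and the complement receptor C5ar1 (2.11 ± 0.11) rose, and Lyz2 (-0.87 ± 0.10), Cebpa (-1.42 ± 0.09), Cybb (-0.79 ± 0.09) and Ptprc (-0.32 ± 0.09) fell. Monocyte markers fell in 10 of 14 cases and rose in 3 (10 and 3 adjusted over the list alone, median -1.04, adjusted p = 1.22e-05, and adjusted p = 0.0458 with an estimated correlation), and their sum went from 11953 ± 109.5 to 8214 ± 523 CPM (exact p = 0.0286). Ace (-4.46 ± 0.11), which encodes angiotensin-converting enzyme, and Chil3 (-2.40 ± 0.10) fell, and Ly6c2 (1.44 ± 0.07), Ms4a4c (1.21 ± 0.11) and Vcan (1.26 ± 0.15) rose. An exact p of 0.0286 is the smallest that 4 against 4 libraries allow, and its Benjamini-Hochberg value over the 16 sums was 0.0381.

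Stromal markers summed to 159 ± 5.54 CPM in Mac and 503 ± 327 in E-Mac (exact p = 0.0286), with 754 and 815 in E-Mac 2 and 4 and 234 and 208 in E-Mac 1 and 3. Of 26 tested 19 rose and 1 fell (22 and 1 adjusted over the list alone, median 4.87, also with genes at 0 in a group set to their bound, adjusted p = 0.00545, and adjusted p = 0.574 with an estimated correlation). Nt5e (2.54 ± 0.15) rose, to between 19.9 and 28.8 CPM in the 4 E-Mac libraries, and the adhesion molecule Vcam1 (64.6 ± 7.50 CPM in Mac and 16.2 ± 4.67 in E-Mac) fell. Of the 43 genes of the list 12 had 1 CPM or more in Mac. The call of this list was lost without E-Mac 4 and with a filter at 10 CPM in 4 libraries (adjusted p = 0.0521 and 0.356, 2.69e-09 to 0.574 over all alternatives except fry). Without any 1 Mac library the permutation p of the sum was 0.171, with a difference of 342 to 346 CPM, and without E-Mac 2 and 4 the difference of the sums was 61.9 CPM instead of 343.9. Much of the Mac sum was Vcam1 and Runx2, the latter at 47.6 CPM in Mac and 51.4 in E-Mac. The fall of Vcam1 thus lowered these differences. The sum without its highest member, Runx2, and the sum over collagen genes only were also higher in E-Mac (exact permutation test, p under 0.05). Granulocyte markers summed to 37042 ± 1648 CPM in Mac and 15485 ± 3533 in E-Mac (exact p = 0.0286), with 19649 and 17158 in E-Mac 2 and 4 and 12197 and 12936 in E-Mac 1 and 3. The members most abundant in Mac, S100a9 and Ngp, were 9376 ± 649.9 and 7785 ± 259.8 CPM there and 4239.8 ± 1052 and 1394 ± 397 in E-Mac. All 21 genes of this list had 1 CPM or more in Mac, and 13 fell and 3 rose (13 and 3 adjusted over the list alone, median -0.88, adjusted p = 6.97e-05, and adjusted p = 0.213 with an estimated correlation). Fcnb (-3.40 ± 0.12) and Camp (-2.91 ± 0.14) fell, and Stfa2l1 (0.88 ± 0.17) rose. Cxcr2 (0.58 ± 0.18) and Mmp9 (0.56 ± 0.18) rose with overlapping groups, but not with total counts only (adjusted p = 0.0645 and 0.0690) or upper-quartile factors (0.0518 and 0.0572).

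**Figure D3:**
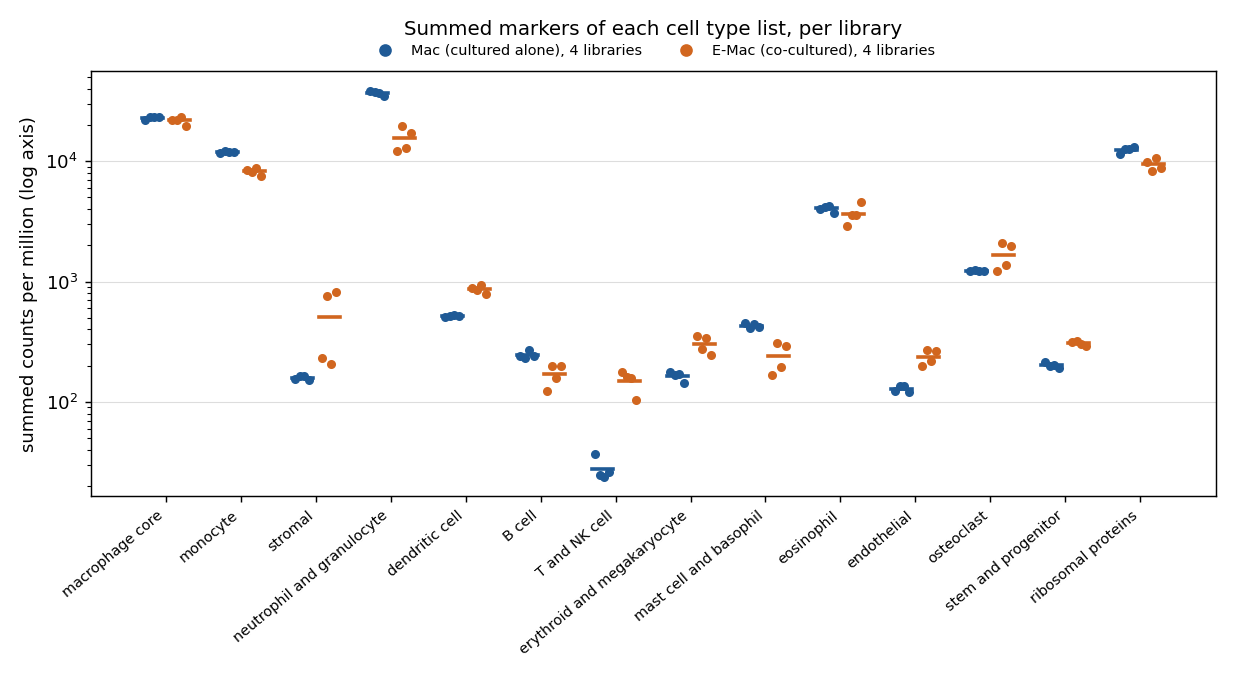
Summed CPM (log axis) over each cell type marker list and the ribosomal proteins, with each point a library and each line a group mean. The stromal sums of E-Mac 2 and 4 (754 and 815 CPM) stand above those of E-Mac 1 and 3 (234 and 208), and the granulocyte sums of all 4 E-Mac libraries lie below those of Mac.

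Dendritic cell markers rose in 6 of 16 cases and fell in 5 (7 and 5 adjusted over the list alone, adjusted p = 0.662), and 5 rose and 6 fell with total counts only. Their median was -0.06, while the sum, led by the interferon-induced Bst2 (2.60 ± 0.10), went from 519 ± 10.7 to 867 ± 62.5 CPM (exact p = 0.0286); Dpp4 (-2.58 ± 0.12), Cd209a, Flt3, Kmo and Clec9a fell. B cell markers rose in 6 of 11 cases and fell in 2 (6 and 2 adjusted over the list alone, median 0.94, adjusted p = 0.580), yet their sum went from 245 ± 17.4 to 169.7 ± 36.4 CPM (exact p = 0.0286). Ighm (-0.74 ± 0.13) and Cd79b fell while the low Pax5 (2.19 ± 0.40) rose. In the T and NK cell list 1 of 9 rose and 4 fell (1 and 4 adjusted over the list alone, median -0.98, adjusted p = 0.580). The interleukin-7 receptor gene Il7r (6.27 ± 0.28), at 138 ± 32.7 CPM in E-Mac, carried the sum from 27.8 ± 6.11 to 149.7 ± 31.3 CPM (exact p = 0.0286), and Cd4 (-2.49 ± 0.29), Gzma, Nkg7 and Ncr1 fell. Without E-Mac 4 the camera direction of this list turned, with no call (adjusted p = 0.877, 0.344 to 0.877 over all alternatives except fry). Mast cell and basophil markers fell in 8 of 10 cases and rose in 0 (8 and 1 adjusted over the list alone, median -1.27, adjusted p = 0.0106, and adjusted p = 0.477 with an estimated correlation). Fcer1a (-2.95 ± 0.30) and Cpa3 (-1.48 ± 0.18) fell, and the sum went from 431 ± 21.4 to 241 ± 69.5 CPM (exact p = 0.0286). The call of the list was lost with a filter at 10 CPM in 4 libraries (adjusted p = 0.0668, 6.26e-05 to 0.477 over all alternatives except fry).

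Erythroid and megakaryocyte markers fell in 9 of 13 cases and rose in 4 (9 and 4 adjusted over the list alone, median -2.24, also with genes at 0 in a group set to their bound, adjusted p = 0.0218, and adjusted p = 0.144 with an estimated correlation). The globin genes Hbb-bs and Hba-a1 fell to 0 counts, but the platelet chemokines Ppbp and Pf4 rose, as did Tfrc (1.33 ± 0.12) and, with overlapping groups, Gata1, and the sum went from 164 ± 13.7 to 304 ± 52.5 CPM (exact p = 0.0286). The list did not pass without E-Mac 4, with the replicate number as a block, with total counts only or with a filter at 10 CPM in 4 libraries (adjusted p = 0.191, 0.347, 0.0514 and 0.944). Nor did it pass without E-Mac 2 and 4 (adjusted p = 0.818, 0.00359 to 0.944 over all alternatives except fry), when the camera direction turned although 9 of 14 members fell and 3 rose. Eosinophil markers fell in 6 of 10 cases and rose in 2 (6 and 2 adjusted over the list alone, median -0.60, adjusted p = 0.0430, and adjusted p = 0.532 with an estimated correlation). The ribonuclease genes Ear1 (-1.77 ± 0.10) and Ear2 (-1.39 ± 0.08) fell, Ccr3 (1.84 ± 0.25) and, with overlapping groups, Alox15 rose, and the sums were 4049 ± 227 and 3658 ± 702 CPM (exact p = 0.314). The eosinophil call was lost without Mac 2 or E-Mac 1 (adjusted p = 0.0548 and 0.112) and with the replicate number as a block (0.0652). It was also lost with total counts only, upper-quartile factors or a filter at 10 CPM in 4 libraries (0.0580, 0.0582 and 0.0847, 0.00477 to 0.532 over all alternatives except fry).

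Endothelial markers rose in 3 of 8 cases and fell in 4 (3 and 4 adjusted over the list alone, adjusted p = 0.578); their median was -0.28 although the camera direction was up. The VEGF receptor gene Kdr (4.37 ± 0.14), Pecam1 and Cdh5 rose, the transcription factor Erg (-2.31 ± 0.21), Flt1, Vwf and Tie1 fell, and the sum went from 129 ± 8.63 to 238 ± 35.1 CPM (exact p = 0.0286). Osteoclast markers rose in 4 of 9 cases and fell in 2 (4 and 3 adjusted over the list alone, adjusted p = 0.447). Their median of 0.08 was -0.01 with upper-quartile factors and -0.06 with total counts only, and the sums were 1228 ± 8.89 and 1669 ± 433 CPM (exact p = 0.0857). The receptor of the osteoclast factor RANKL, Tnfrsf11a (2.74 ± 0.12), Dcstamp, Ctsk and Mmp9 rose (Mmp9 with overlapping groups), Itgb3 fell, and the fusion gene Ocstamp fell from 1.19 ± 0.355 CPM to 2 counts, both in E-Mac 2 (0 without that library), a ratio of 32.4 (95% counting interval 8.64 to 273). Stem and progenitor markers fell in 7 of 13 cases and rose in 3 (7 and 3 adjusted over the list alone, median -0.99, also with genes at 0 in a group set to their bound, adjusted p = 0.324). Their sum went the other way, from 201 ± 9.80 to 308 ± 11.5 CPM (exact p = 0.0286), carried by the interferon-responsive Ly6a (3.99 ± 0.10); Procr and Cd34 rose too, while Flt3 (-2.46 ± 0.19) fell.

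Ribosomal protein genes fell in 26 of 30 cases and rose in 0 (26 and 0 adjusted over the list alone, median -0.39, adjusted p = 0.00182, and adjusted p = 0.578 with an estimated correlation), with Rps24 (-0.58 ± 0.07) as an example. Their sum went from 12385 ± 705 to 9404 ± 1023 CPM (exact p = 0.0286). The 37 mitochondrially encoded transcripts had 0 counts in each library. Of the sex-linked transcripts Xist, the X-inactivation RNA of female cells, was detected in all 8 libraries and fell (-0.59 ± 0.10, adjusted p = 0.000230), and Ddx3y, Uty, Kdm5d and Eif2s3y of the Y chromosome had 0 counts in each. The first principal component held 79.5% of the variance and separated Mac from E-Mac, and the second held 6.73% and set E-Mac 2 and 4 (20.6 and 28.9) apart from E-Mac 1 and 3 (-26.2 and -22.0). Counting intervals and floors cover counting error only.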

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

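The tests of the stromal markers, the granulocyte markers and the splits of the libraries were chosen only after the results had been seen, and the parts and the second granulocyte test were added after the first tests. Of 273 groups of 4 values, 14 held a library far from the other 3, and chance gives about 1 in 20, or 13.65. Mac 2 had 0.666 CPM of Ccl7, against 0.123 to 0.186 in the other Mac libraries, 114 CPM of Abca9 (others 126 to 127), and 11646025 total counts (others 15096159 to 15556935). Mac 3 alone had counts of Ppbp and of Col5a2, at 0.123 CPM each, with 0 in the others. Mac 4 had 149 CPM of Srebf2 (others 137 to 139) and 551 of Adam8 (others 638 to 651). Mac 1 had a macrophage core sum of 21875 CPM (others 23102 to 23300) and a T and NK cell sum of 36.9 (others 24.0 to 26.0). E-Mac 4 had 60.2 CPM of Cdk2 (others 52.8 to 53.8), 389 of Mmp14 (others 548 to 578) and 184 of Ly6a (others 221 to 223). E-Mac 2 alone had counts of Ocstamp (0.138 CPM, others 0), and E-Mac 1 had 0 CPM of Cxcl12 (others 0.269 to 0.288).

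Stromal markers rose in E-Mac, with the largest sums in E-Mac 2 and 4, and RNA of stromal cells carried through the macrophage sort, which would remove such cells if it were complete, would raise all of them in 1 proportion. Over the 12 markers that were called higher and had 10 CPM or more, the log2 ratio of the excess in E-Mac 4 to that in E-Mac 3 had a median of 3.22 and an SD of 1.80, above the bound of 1.61, which argues against carried-over RNA as the whole cause for the 12 together. For the 7 markers under 1 CPM in Mac (Fbn1, Col5a2, Col1a2, Sparc, Lox, Bgn and Col3a1) the SD was 0.35 around a median of 3.31. Those 7 thus rose in 1 proportion, as carried-over stromal RNA would. They were chosen for having risen, and Col3a1 and Col5a2 reached 10 CPM only in E-Mac 2 and 4, so the high median partly follows from the choice. Of the 26 stromal markers tested 6 did not pass and were left out, so the 7 cannot show carry-over. For the 5 at 1 CPM or more (Nt5e, Col1a1, Eng, Col5a1 and Acta2) the SD was 2.49 around 3.12. Nt5e (-0.65) and Eng (-1.85, a small excess over 12.3 CPM in Mac) gave that spread. Col1a1 (3.32), Col5a1 (3.25) and Acta2 (3.12) lay near the 7, so that carried-over RNA stays open for these 3. The ratio of E-Mac 2 to E-Mac 1 gave SDs of 1.34, 0.44 and 1.80 for the 12, the 7 and the 5, against bounds of 1.30, 1.36 and 1.17. The ratio of E-Mac 4 to E-Mac 3 had a median of -0.38 over the 1218 other genes that rose 2-fold or more in groups that did not overlap. Of these, 818 (67.2%) lay below 0 and 39 (3.20%) at or above 1.61, so carried-over stromal RNA cannot account for most of the 1218. The 39 included Hspg2 (3.90), Fbln2 (3.86), Nid1 (3.42) and Tnc (3.40), each at 0.0618 to 0.145 CPM in Mac. They also included Gfod1 (1.76), at 60.9 CPM in Mac. Carried-over RNA stays open for the 39, of which these were picked after their values had been seen. Collagen expression by the macrophages themselves stays open as well and was not tested.

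Granulocyte markers fell in E-Mac, in cells sorted by markers that are not given in the sources used here. A lower share of granulocytic cells as the only change would leave no abundant marker higher. Of the 18 markers with over 100 CPM in Mac, 2 (Cxcr2 and Mmp9) were higher with TMM or RLE factors. With upper-quartile factors or total counts only 0 were. Their log2 fold changes were 0.58 and 0.56 with TMM factors and 0.43 and 0.41 with total counts only. In E-Mac 2 and 4 Cxcr2 was 556 and 543 CPM and Mmp9 1749 and 1616. E-Mac 1 and 3 held 312 and 346 CPM of Cxcr2 and 922 and 1075 of Mmp9. Mmp9 is also in the osteoclast and matrix protease lists, so other cells may raise it while granulocytic cells become fewer. A lower share of granulocytic cells therefore cannot be told apart from other causes by that test. The requirement that all 4 scalings give the call was set after the result had been seen. One lower share acting alike on all markers is argued against by the SD of their log2 fold changes, 1.20, against a largest standard error of 0.273. A loss of some kinds of granulocytic cell, and a change of expression within the cells, stay open; how much of each marker comes from granulocytic cells was not measured.

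For the count of differing genes, 1 of 35 splits of the 8 libraries into 4 and 4, the real one, gave as many as 7814. That is the smallest share these splits allow, and it argues against a chance division of the libraries. The highest other split gave 0, but each other split mixes Mac and E-Mac, so their difference adds to its spread within groups. The labels do not say that the libraries are separate cultures, so the splits cannot exclude a difference between cultures. The 2695 genes with 2-fold changes gave the same result (1 of 35, highest other 0). The splits cannot exclude a chance division for the number of shifted lists, where 2 of 35 gave as many as 27. Mac 1, Mac 2, Mac 4 and E-Mac 4 against the rest gave 28. That split holds 3 Mac libraries on one side and so keeps part of the real difference, and splits of this kind gave 19 to 28 lists. The count of lists thus cannot decide the question. Splits with 2 Mac libraries on each side gave 1 to 13 lists, although 0 genes differed in them. Camera with the preset correlation of 0.01 can thus call lists where no gene is called. The estimated correlations ran from -0.0618 for endothelial markers to 0.811 for ribosomal proteins, with 0.264 for type I interferon and 0.758 for cell cycle.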

How the results depend on the processing

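Leaving out E-Mac 2 and 4 was chosen only after the result had been seen; the other alternatives were planned. The 7814 genes ranged from 7233 to 7986 when 1 library was left out, the 2695 with 2-fold changes from 2718 to 2898 and the 27 shifted lists from 26 to 29, and no other setting moved the gene count by over 1.5 times. With at least 10 CPM in 4 libraries 1429 genes changed 2-fold, since fewer genes were tested. With the replicate number as a block 7458 genes differed, 2664 by 2-fold, and 7376 of the 7814 kept their call and direction. Across genes, deviations from the group mean of libraries that share a number had correlations of -0.04, 0.03, 0.01 and -0.11. Pairs of unlike number had values such as -0.09 and 0.12 (Mac 1 with E-Mac 3 and with E-Mac 4). No pairing by number was seen, but a shared animal or day that leaves no such trace cannot be excluded. Within E-Mac, libraries 1 and 3 (0.058) and libraries 2 and 4 (0.061) were more alike than the other pairs (-0.57 to -0.49). The tests treat the 4 E-Mac libraries as independent, so p-values may be too small if these are 2 pairs. Leaving out E-Mac 2 and 4 keeps the pair of 1 and 3 and so may also narrow the spread within E-Mac. The block ended the calls of the erythroid and eosinophil lists (adjusted p = 0.347 and 0.0652), and Ptgs2 gained one (-0.41, adjusted p = 0.0393). With the stromal score as a covariate 5611 genes differed, 4532 of them among the 7814 with the same sign and 38 with the opposite sign. The score nearly follows the groups, and that setting ended the calls of Hba-a1, Ocstamp, Pax5 (log2 fold change 2.19 before and 0.65 with it), Il1b (1.31 and 0.78), Xist (-0.59 and -0.60) and Tnf (1.01 and 1.16). Xist and Tnf lost the call at no smaller a fold, and Hba-a1 and Ocstamp had too few counts in E-Mac for a usable fold. Mrc1 (2.19, adjusted p = 0.000856) and Csf1r (0.44, adjusted p = 0.0229) gained a call. With an estimated correlation 7 lists kept their call, and the adjusted p of the others among the pathway lists became classical activation 0.108, chemokines 0.0509, NF-kB regulators 0.215, immediate early 0.574, MHC class II 0.304, lysosome 0.357, glycolysis 0.158, cholesterol synthesis 0.145, LXR targets 0.167, unfolded protein response 0.543, cell cycle 0.532, trophic factors 0.158 and apoptosis 0.120. Without E-Mac 2 and 4 the adjusted p was 0.102 for immediate early genes and 0.150 for MHC class II, with medians of -1.01 and -1.15 against -0.94 and -0.96, and it was 5.26e-06 for alternative activation, 0.00501 for phagocytic receptors and 0.0403 for the respiratory chain, and the camera directions of the B cell, T and NK cell and erythroid lists turned (0.840, 0.818 and 0.818), although 3 rose and 2 fell, 2 rose and 8 fell, and 3 rose and 9 fell in them. Lists that camera called under a setting that keeps all 8 libraries and not in the reported test were alternative activation (block 0.00319), STAT3 (no filter 0.00388), the respiratory chain (no filter 0.0410) and receptors for stromal signals (no filter 0.00420). The fry test asks whether a list's genes move on balance 1 way, or in either direction, and not whether they differ from other genes, so it does not bear on the camera calls. It called 34 lists for 1 direction, with adjusted p of 0.00424 for alternative activation, 0.00116 for STAT3, 0.0217 for phagocytic receptors and 0.000152 for receptors for stromal signals, and 39 of 39 for either direction. The camera direction of the cAMP list turned at 10 CPM (0.886) and with the block (0.802). With 1 library left out, the adjusted p ran from 0.0125 to 0.314 for alternative activation, 0.425 to 0.949 for cAMP, 0.0341 to 0.0969 for STAT3, 0.000383 to 0.0898 for MHC class II, 0.0256 to 0.392 for phagocytic receptors, 0.00889 to 0.0625 for trophic factors, 0.0323 to 0.0897 for receptors and 0.344 to 0.877 for T and NK cells. The log2 fold change of Mrc1 then ran from -0.21 to 0.40, that of Il6 was -0.93 with the covariate, and that of Csf1r -0.042 with upper-quartile factors and -0.087 with total counts only. The stromal sum differed by 239.8 to 442 CPM with 1 library left out, and by 61.9 without E-Mac 2 and 4, where the exact p was 0.0667, the smallest that design allows. Unless given, the cause was not tested. Of the named genes' values 970 with 1 library left out and 1314 under the other settings kept their direction and side of the threshold, and 3 and 7 lost the call, 2 and 6 gained one and 1 and 3 turned. Of the lists' values 294 and 337 kept both, 8 and 31 lost the call, 7 and 14 gained one and 3 and 5 turned. The counts under the other settings include fry for 1 direction, which asks another question. Gains under fry were those of alternative activation, STAT3, phagocytic receptors, receptors for stromal signals, and the endothelial, osteoclast and stem and progenitor lists. Genes with few counts are limited by depth, as the intervals of Ppbp, Col5a2 and Ocstamp show.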

Other observations

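The 9 gene lists described first here were chosen after the main results had been seen, and the values of some members, among them C3ar1, Alox5ap and those that the fixed lists also hold (0 to 6 in each list) had been seen too. The glucocorticoid test was written before its result was seen, though after Fkbp5, Tsc22d3 and Per1 had been. Guanylate-binding proteins and immunity-related GTPases, interferon-induced proteins that act against pathogens inside cells, rose almost throughout: 13 of 14 rose and 0 fell (median 2.15, adjusted p = 7.44e-23, and adjusted p = 0.00182 with an estimated correlation). Igtp (2.19 ± 0.07) and Gbp2 (2.28 ± 0.08) were among them, and only Gbp8 (0.04 ± 0.13) did not pass. Of the TGF-beta target genes 12 of 14 rose and 1 fell (median 1.59, adjusted p = 1.51e-07, and adjusted p = 0.0296 with an estimated correlation). The inhibitors of the pathway Skil (1.84 ± 0.07), Tgif1 (1.80 ± 0.08) and Smad7 (16.3 ± 0.633 CPM in Mac and 32.5 ± 2.69 in E-Mac) rose and Bambi (-0.82 ± 0.19) fell. In amino acid transport and serine and asparagine synthesis 10 of 16 rose and 2 fell (adjusted p = 0.000121, and adjusted p = 0.206 with an estimated correlation). Slc3a2 (2.83 ± 0.10), which pairs with several amino acid transporters, Slc7a5 (2.01 ± 0.15) and Phgdh (2.10 ± 0.18) rose, while Slc1a5 (-0.53 ± 0.09) and Slc38a2 (-0.29 ± 0.06) fell. Among Toll-like receptors and their adaptors 14 of 20 rose and 3 fell (median 0.54, adjusted p = 0.00408, and adjusted p = 0.206 with an estimated correlation). Tlr3 (1.93 ± 0.16) and Tlr1 (1.46 ± 0.12) rose and Ticam2 (-1.19 ± 0.14), Tlr8 (-0.61 ± 0.09) and Irak4 (-0.48 ± 0.08) fell.

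The 5 others did not pass as lists. For inflammasome genes 7 of 14 rose and 4 fell (adjusted p = 0.311), the latter Nlrp1b, Naip5, Nlrc4 and Nek7. Complement genes went both ways, as 6 of 15 rose and 5 fell (adjusted p = 0.760). The complement receptor C3ar1 (5.01 ± 0.15) reached 801 ± 151 CPM, whereas the central component C3 (-1.46 ± 0.07), Cd55, C4b and C1qa were among those that fell. For eicosanoid synthesis 7 of 13 rose and 2 fell (adjusted p = 0.193), with Pla2g7 (1.90 ± 0.09) up and Lta4h (-0.97 ± 0.06) and Ptges2 down. For integrins 7 of 15 rose and 5 fell (adjusted p = 0.330), with Itga5 (1.53 ± 0.09) up and Itga9 (-1.85 ± 0.16), Itgal, Itga4, Itgb3 and Itga2 down, and for p53 targets 6 of 14 rose and 1 fell (adjusted p = 0.201), the latter Btg2. The genes named from the 9 lists were chosen after their values had been seen.

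Fkbp5 (-3.29 ± 0.07), Tsc22d3 (-2.99 ± 0.08) and Per1 (-1.88 ± 0.16), which glucocorticoids induce, fell in E-Mac. As a hypothesis, E-Mac may respond less to glucocorticoid. Of 17 tested genes of a list of other glucocorticoid-induced genes 9 fell, 3 rose and 5 did not pass, with a median log2 fold change of -0.38 (camera p = 0.00136, and p = 0.0871 with an estimated correlation). Klf9 (-2.63 ± 0.13) and Glul (-2.01 ± 0.07) fell, while Errfi1 (2.11 ± 0.18), Sgk1 (0.67 ± 0.13) and Sesn1 (0.55 ± 0.09) rose. The values the hypothesis needs are there with the preset correlation, but the culture's glucocorticoid content is not given in the sources used here, and other regulators of these genes were not tested.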
